A study of Danio rerio with 3 samples.

How the data were processed

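Macrophages carrying an mpeg reporter were sorted from whole zebrafish embryos at 5 days post fertilization into 384-well plates and processed with CEL-Seq2, per the labels' protocols. CEL-Seq2 barcodes the RNA of each well, amplifies it linearly and reads the 3′ end of each transcript with a unique molecular identifier (UMI), so that reads from 1 molecule are counted once. The embryos were mutants for ptpn6, the gene of the protein tyrosine phosphatase Shp1, or their siblings, and the labels do not divide the siblings by genotype. Of the 3 plates, the plate of sort day 1 held siblings in well rows A to H and mutants in rows I to P, and on sort day 2 each genotype had a plate of its own. On sort day 2 the genotype and the plate therefore cannot be told apart. The number of embryos behind each plate is not given in the sources used here.

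The deposited tables hold expected counts per gene and well, which the authors had corrected for molecules that drew the same UMI. This unit was read from the values: 100% of the values above 0 in each table became whole numbers, within 0.005, when that correction was inverted. The submitters' processing notes name the aligner BWA and the genome build Zv9 without a version, and the counting and annotation steps are not given in the sources used here. No scaling for depth had been applied, since wells summed to different totals. The 88 spike-in IDs were kept apart from the genes.

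Symbols came from a table of gene names that matched 17027 of 21915 IDs, and those IDs held 75.9% of the UMIs. A single ID without a symbol held 9.995% of the UMIs. A gene list member was first matched by its zebrafish symbol and otherwise by the symbol without its paralogue letter, a fallback added after the names had been seen. Several genes that share a symbol are therefore printed with their ID. Genes of families with near-identical copies, such as the si:dkey, mfap4, ccl34b and heat shock genes, are uncertain, because the counting could have split their reads.

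The columns carry well numbers 1 to 384 and no well names. Numbers were read row by row from A1, under a condition set before the data were examined: the 8 corner wells that this protocol usually leaves without a cell had to hold a median under 0.1 of the plate median in 2 of the 3 plates. Without spike-ins the ratios were 0.0591 on the shared plate, 0.799 on the mutant plate and 0.0890 on the sibling plate of sort day 2, so the condition was met. With spike-ins they were 0.335, 0.944 and 0.328 and would not have met it; leaving spike-ins out was settled after both sets had been seen. In the mutant plate the median well held only 207 UMIs, and 8 of the 8 corner wells held under 500. Wells with at least 1000 UMIs were also spread unevenly over the 24 columns of a plate, with numbers read row by row. The one-sided permutation p was 0.017, 0.0003 and 0.0001 for the shared, mutant and sibling plate, the last the smallest that the permutations can give. Over 16 rows, with numbers read column by column, no such unevenness was detected (one-sided permutation p of 0.48, 0.32 and 0.33).

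Wells with at least 1000 UMIs were kept: 131 of 192 sibling wells and 138 of 192 mutant wells on sort day 1, and 199 of 384 sibling wells and 125 of 384 mutant wells on sort day 2. No doublet caller was run on these sorted wells; leaving out the 2% of wells with most UMIs in each plate was an alternative. Counts were scaled per well, log transformed and standardized within each plate, because clustering without that step separated the wells by plate. Standardizing removes from the clustering what differs between the 2 plates of sort day 2, the mean effect of genotype included. From the 2000 most variable genes, 20 principal components and 15 nearest neighbours were used for Leiden clustering at resolution 1. A marker counted as detected in a cluster when at least 25% of its wells held a UMI. A cluster took the name of a class when at least 2 of its fixed markers stood among the cluster's 10 leading genes and 3 were detected. It was called macrophage-like when at least 3 macrophage markers were detected, no other class had more markers among the 10 leading genes, and a cluster of low depth also had a macrophage marker there. Other clusters stayed unnamed. The clustering scheme and this naming rule were chosen after looking at the data; the markers were fixed before.

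UMIs were summed over the macrophage-like wells, and over all wells kept, of each genotype and sort day, which gave 4 pools, and the sums were rounded to whole numbers. The pool is the unit of every test, since cells are not replicates. With 2 pools per genotype an exact test of any single value cannot give a p below 0.333, and p-values measure only the spread between these pools, which may be technical. Genes were tested with edgeR's quasi-likelihood test on genotype alone, with TMM scaling, its default filter on low counts and Benjamini-Hochberg adjustment at 0.05. The labels give pools of the same sort day a shared day, so a fit with sort day as a block was the alternative set before the data were seen and is printed beside a result where it changes a call. Pools of the same day deviated together: the correlation, across genes, of their differences between days was 0.225 in macrophage-like wells and 0.124 over all wells kept.

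Of 30 gene lists fixed before the data were examined, 21 had at least 3 members among the genes tested in macrophage-like wells and were tested with limma's camera at its preset correlation, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry asks whether a list's genes move one way on balance or, in its mixed form, in either direction. The genes named were ptpn6; up to 12 higher and 12 lower genes with the largest log2 fold among those that passed, moved the same way on both days and averaged at least 20 CPM, with places left filled first from the fit with sort day; and up to 4 members of each list with the smallest p. Well shares have exact Clopper-Pearson 95% intervals and UMI counts exact Poisson 95% intervals, with a floor of 3 counts where none was seen; both cover counting error only.

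The tests were tried on simulated pools drawn from the real means, totals and spread. In macrophage-like wells (4740 genes) the genotype fit recovered 10% of genes changed by a log2 fold of 1, 78% at 2, 98% at 3 and 100% at 4, with 13 false calls, and the fit with sort day recovered 6%, 68%, 100% and 98%, with 1 false call. Over all wells kept (8177 genes) the genotype fit recovered 0%, 38%, 88% and 100%, with 7 false calls, and the fit with sort day 6%, 58%, 94% and 98%, with 8 false calls.

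Alternatives set before the data were seen were DESeq2, its size factors within edgeR, no filter on low counts, sort day as a block, leaving out each pool in turn, UMI minima of 500 and 2000, leaving out the 2% of wells with most UMIs, thinning every pool to the smallest total, and Leiden resolutions of 0.5 and 2. Alternatives added after seeing the data were leaving out wells rich in RNA of other tissues (0.5% or more of their UMIs), adding microglia-like wells, leaving out the abundant ID without a symbol, and clustering without the 30 leading genes of the macrophage-like clusters, which include genes that differ between the genotypes. A table of gene positions from another assembly, GRCz12tu, was used only for which genes neighbour ptpn6. The software was Python 3.11.15 with leidenalg 0.10.2 and scikit-learn 1.9.0, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.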

Results

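Shp1, the phosphatase encoded by ptpn6, has SH2 domains and dampens signalling downstream of cytokine and immune receptors. The series asked what this phosphatase does in early blood development, here in mpeg-positive macrophages of ptpn6 mutant zebrafish and their siblings at 5 days post fertilization. Gene expression was counted as UMIs per well on 3 plates, which gave 4 pools of wells: siblings and mutants of sort day 1, from 1 shared plate, and siblings and mutants of sort day 2, from 1 plate each. The wells kept held 1121213 UMIs in siblings and 1406635 in mutants of day 1, and 2185636 in siblings and 1290186 in mutants of day 2. The median well held 6890, 8107, 9680 and 9964 UMIs in the same order, on 1817, 2059, 2070 and 2221 genes. Cells are not replicates, so wells were summed and n is 2 pools per genotype throughout.

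Transcripts of ptpn6 (ENSDARG00000089043) were rare in both genotypes, with fewer UMIs in mutants on both days. Over all wells kept, siblings held 11 UMIs on day 1 (95% Poisson interval 5.49 to 19.7) and 3 on day 2 (0.619 to 8.77), and mutants held 5 (1.62 to 11.7) and 0 (up to 3.69). These counts correspond to 9.81 and 1.37 CPM in siblings and to 3.55 and 0 CPM in mutants, where the interval of the count of 0 reaches 2.86 CPM. The fitted log2 fold, mutant over sibling, was -1.58 (SE 1.58), which did not pass (p = 0.346 by the quasi-likelihood test of edgeR, not an exact test), and it turned to 0.23 without the siblings of day 1. In macrophage-like wells siblings held 2 and 1 UMIs and mutants 0 and 0, too few for a fold. The labels do not describe the lesion, and a 3′ count checks the genotype only if the lesion lowers the mRNA.

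The sorted wells fell into macrophage-like, microglia-like and mesenchyme-like classes and an unnamed remainder. Of the macrophage-like clusters, those led by ctsk (91 wells) and ccl34b.8 (40) had 0 macrophage markers among their 10 leading genes and the one led by mfap4 (123) had 1. The name rests on 11, 12 and 12 markers detected. Detection does not set these clusters apart, since 12 were detected in the microglia-like, 10 in the mesenchyme-like and 10 in the largest unnamed cluster. Macrophage-like wells made up 36.6% of siblings (48 of 131 wells, 95% Clopper-Pearson interval 28.4 to 45.5) and 36.96% of mutants (51 of 138, 28.9 to 45.6) on day 1, and 48.7% (97 of 199, 41.6 to 55.9) and 46.4% (58 of 125, 37.4 to 55.5) on day 2. Microglia-like wells, led by apoeb and apoc1, apolipoprotein genes of brain macrophages, made up 13.7% and 14.5% on day 1 and 18.6% (13.4 to 24.7) on day 2 in siblings, and 13 of 125 mutant wells of day 2 (interval 5.65% to 17.1%). Mesenchyme-like wells, led by the collagen genes col1a2 and col1a1a, made up 3.05% of siblings and 2.17% of mutants on day 1, and 4.02% (1.75 to 7.77) and 12.8% (7.50 to 19.95) on day 2. Mesenchyme markers went the other way over all wells kept of day 2, at 0.0400% of the UMIs in siblings and 0.0152% in mutants. The class was set after standardizing within each plate, so these shares do not show more mesenchyme RNA in mutants. The genotypes' intervals overlapped within each day for macrophage-like and microglia-like wells, and narrowly for mesenchyme-like wells of day 2. Without the 2% of wells with most UMIs the latter were 0.513% (up to 2.82) and 12.3% (from 7.05), with no overlap. At resolution 0.5 they were 1.51% (up to 4.34) and 11.2% (from 6.26), again with none. Resolution 2 (up to 6.45 and from 7.50) and clustering without leading genes (up to 7.11 and from 7.50) gave none either. The intervals overlapped at a minimum of 500 UMIs (up to 7.66 and from 6.98). At 2000 UMIs the shares were 3.70% (up to 7.48) and 7.76% (from 3.61), with a wide overlap. No exact test of 2 pools against 2 can pass 0.05. Unnamed wells held 46.6% and 46.4% on day 1 and 28.6% and 30.4% on day 2. The largest unnamed cluster, of 116 wells, was led by pdk2, cxcr4, noct and cnksr1, with the neutrophil markers lyz and npsn and the cell cycle genes plk1 and mki67 among its 10 leading genes; 799 of the UMIs of lyz came from mutants of day 2 and 9 from all other pools. The sort gate, the UMI minimum and the lower number of wells kept on the mutant plate of day 2 can set these shares.

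**Figure D1:**
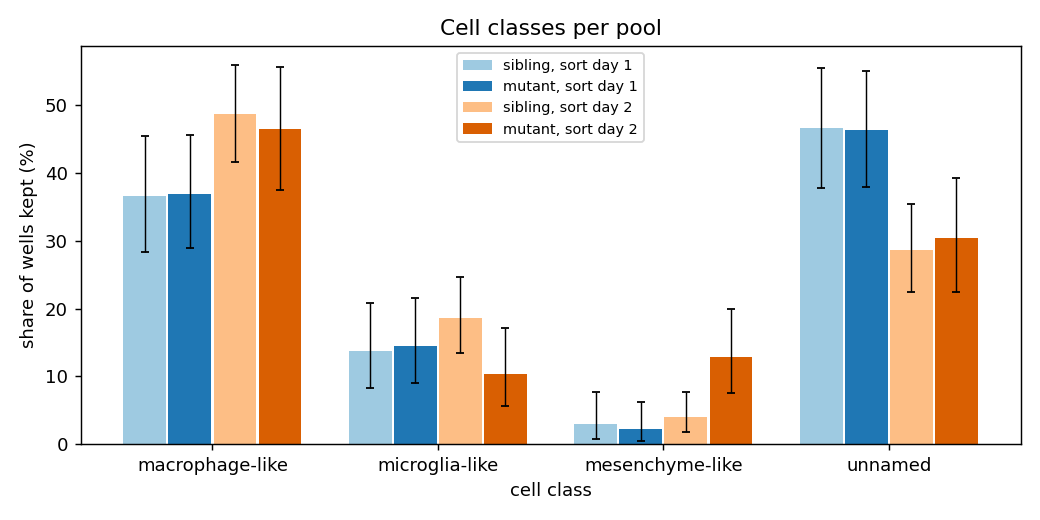
Share of the wells kept (%) in each cell class, per pool; bars are shares and error bars exact 95% binomial intervals, which cover counting error only. On sort day 2 mesenchyme-like wells stand at 4.02% in siblings and 12.8% in mutants, while mesenchyme markers held 0.0400% and 0.0152% of the UMIs kept.

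In macrophage-like wells, 3 genes rose in mutants and none fell, of 4740 tested. The uncharacterized gene si:dkey-6n3.3 had 78.7 CPM (TMM-scaled) in siblings and 1485 in mutants on day 1, and 54.3 and 5609 on day 2. Its log2 fold was 5.76 (SE 0.61, adjusted p = 0.00778, edgeR). The gene anxa5b, for the phospholipid-binding protein annexin A5, rose by a log2 fold of 5.59 (SE 0.65, adjusted p = 0.00778), with 4 and 109 UMIs on day 1 and 3 and 266 on day 2. The uncharacterized si:dkey-119g10.4 rose by 4.76 (SE 0.55, adjusted p = 0.00778), from 31 to 650 UMIs on day 1 and from 91 to 2632 on day 2. On day 1 a few wells held much of the signal: 3 of the 51 mutant wells held 502 of 920 UMIs of si:dkey-6n3.3, seen in 37 wells, and 416 of 650 of si:dkey-119g10.4, seen in 35.

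With sort day as a block, 40 genes were higher and 20 lower at an adjusted p under 0.05, against 3 and 0 without it. That fit leaves few residual degrees of freedom per gene, so its p-values rest mainly on spread borrowed across genes (prior degrees of freedom 15.7). The block also cannot remove the plate difference of day 2. The 3 genes above were among the 40 higher. The 9 other higher genes named here passed with the block and not in the fit on genotype alone. Among these, ccl34b.8, a chemokine gene, had 3 and 0 UMIs in siblings and 61 and 81 in mutants, a ratio of pooled CPM of 54.7 (95% interval of counting error 18.3 to 268). Its fitted log2 fold was 5.35 (SE 0.86, adjusted p = 0.0773 without and 0.00194 with the block). A second annexin gene, anxa2, was higher by 4.41 (SE 0.84, adjusted p with the block 0.00601), from 11 to 64 UMIs and from 7 to 392. The heat shock chaperone genes hsph1 and hspa2 were higher by 3.53 (SE 0.83) and 3.24 (SE 0.54), and src, which encodes a tyrosine kinase, by 3.19 (SE 0.55), with adjusted p of 0.0117, 0.00649 and 0.00668 with the block. A few wells carried the chaperone genes: on day 1, 3 mutant wells held 59 of 62 UMIs of hsph1 and 35 of 41 of hspa2, and hsph1 was seen in 6 of 51 mutant and 6 of 48 sibling wells. On day 2, 3 mutant wells held 24 of 45 and 55 of 73. Of ccl34b.8, 3 mutant wells held 45 of 61 UMIs on day 1. The serine protease gene fap, the immune checkpoint gene cd276, the Hippo pathway gene mob1bb and an unnamed gene (ENSDARG00000033660) were higher by 4.07, 3.21, 3.25 and 3.98, with adjusted p of 0.0193, 0.0295, 0.0351 and 0.00482 with the block.

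The 12 lower genes named passed with sort day as a block and not in the fit on genotype alone. Of them, si:ch211-284o19.8, lacc1, pglyrp5 and mfap4 were among the 10 leading genes of 1 macrophage-like cluster. That cluster was the largest in the sibling pools and not in the mutant pools. A different mix of clusters could thus give their falls, and the genes were not tested within clusters. A gene of mfap4, a marker of zebrafish macrophages (ENSDARG00000088745), had a log2 fold of -1.72 (SE 0.34, adjusted p = 0.102 without and 0.00760 with the block). For lacc1, an enzyme of macrophage metabolism, it was -1.32 (SE 0.37; 0.0345 with the block), for pglyrp5, a peptidoglycan recognition protein, -1.83 (SE 0.33; 0.00576), and for ncf1, a cytosolic subunit of the NADPH oxidase, -1.22 (SE 0.30; 0.0154). The prostaglandin synthase gene ptgs2 (ENSDARG00000004539) went from 63 to 18 UMIs on day 1 and from 69 to 11 on day 2, a log2 fold of -2.34 (SE 0.55; 0.0164), and 3 sibling wells of day 1 held 39 of its 63 UMIs. Values for inhba, an activin subunit (ENSDARG00000012671), timp2, a metalloproteinase inhibitor (ENSDARG00000075261), and xkr8.2, of a family of lipid scramblases, were -2.54, -2.29 and -2.04; for inhba, 3 sibling wells of day 1 held 25 of 28 UMIs. The chemokine gene ccl34b.1 and the annexin gene anxa3b stood at -1.21 and -1.87, and the uncharacterized si:ch73-173p19.1 and si:ch211-284o19.8 at -2.79 and -1.97; adjusted p with the block over these 7 genes ran from 0.00116 to 0.0338.

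**Figure D2:**
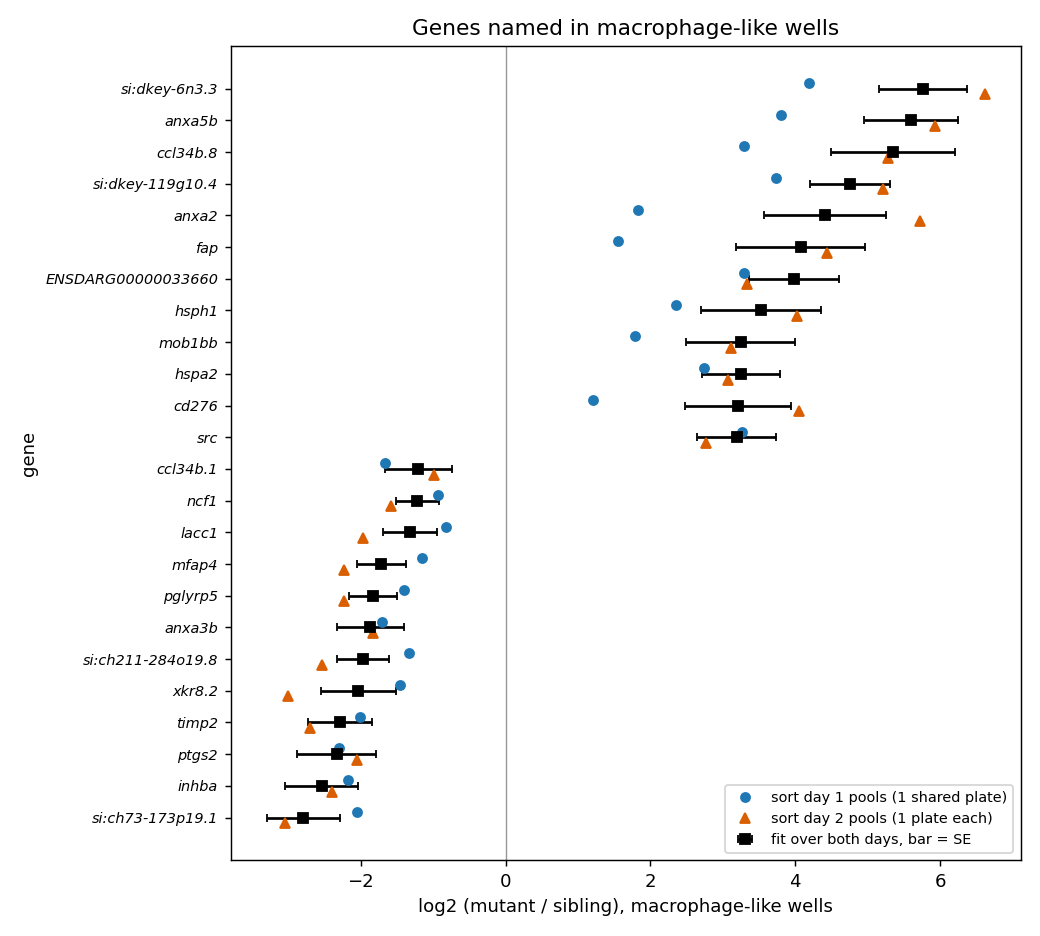
Log2 ratio of mutant to sibling pools for the 24 named genes in macrophage-like wells, one gene per line. Squares are the fitted log2 fold with its SE as the bar, and circles and triangles are sort days 1 and 2. Both days lie on the same side of 0 for every gene, which the rule for naming genes required.

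Across all 4740 genes the log2 ratios of the 2 days correlated weakly (Pearson r = 0.216, Spearman rho = 0.138, across genes, which are not independent replicates), with 54.8% in the same direction. The largest cluster of macrophage-like wells was one led by si:ch211-284o19.8, mfap4 and lacc1 in siblings (31 of 48 wells on day 1, 63 of 97 on day 2), one led by ccl34b.8, tinagl1 and slc7a11 in mutants of day 1 (25 of 51) and one led by gdpd3b, ctsk and ctsl.1 in mutants of day 2 (30 of 58). Since some named genes lead these clusters, the wells were clustered again without the 30 leading genes. The 3 calls stayed, and 60 of the 60 calls with sort day were among the 121 then made. The pools then held 46, 52, 100 and 61 macrophage-like wells, close to the 48, 51, 97 and 58 before. Because the tests sum all macrophage-like clusters, this cannot tell whether a different mix of clusters gave the calls. At a minimum of 2000 UMIs per well no gene passed, and the 3 genes then had adjusted p of 0.0756, 0.0756 and 0.106 with log2 folds of 6.13, 5.48 and 5.02. Fits without 1 pool tested 5478 to 5737 genes, since the filter then admits genes counted in a single pool. Their calls are not comparable with these. On the mutant plate of day 2, wells with under 500 UMIs also held si:dkey-6n3.3, at 4632 CPM.

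Of the 21 gene lists tested, ribosomal protein genes and inflammatory genes were lower and nuclear genes of oxidative phosphorylation higher in mutant macrophage-like wells, at camera's preset correlation. With an estimated correlation none of the 21 lists was called, at adjusted p from 0.817 (for each of these 3) to 0.911. Lists of low correlation did not pass either, such as interferon genes (estimated correlation 0.0101). That version rests on the few residual degrees of freedom that 2 pools per genotype leave, so almost no list could pass. It therefore cannot decide these calls or those of the lists below. Fry called no list as moving one way. For ribosomal proteins, 68 of 72 members were lower on both days, with median log2 ratios of -0.35 and -0.47 (camera adjusted p = 5.24e-25), while no member passed alone; rpl5 (ENSDARG00000015862) stood at -0.66 (SE 0.25, adjusted p = 0.617). They held 14.6% of the UMIs in siblings and 12.1% in mutants on day 1, and 16.6% and 14.2% on day 2. Without TMM scaling the median of all genes shifted from -0.00 to 0.18, and the ribosomal median from -0.40 (70 of 72 members below 0) to -0.21 (68 of 72).

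Of 14 inflammatory genes 11 had log2 folds below 0 and the list was called lower (camera adjusted p = 0.000992); 6 passed adjusted over the list alone and 0 over all genes. Both ptgs2 and acod1, the itaconate-making enzyme of activated macrophages, passed with sort day as a block, acod1 at -0.95 (SE 0.24; 0.0221 with the block). The NF-kappaB inhibitor gene nfkbiaa stood at -0.68 (SE 0.20, adjusted p = 0.371), and mmp9, a matrix metalloproteinase, went the other way at 2.501 (SE 0.81, adjusted p = 0.482). The list's median log2 ratio was 0.06 on day 1 and -0.75 on day 2, and without the siblings of day 2 its mean turned to 0.13 (adjusted p = 0.571). Of 75 oxidative phosphorylation genes, 28 were higher and 6 lower on both days (camera adjusted p = 0.00535), with medians of -0.07 and 0.49; ndufa8 stood at 1.14 (SE 0.50) and sdhaf4 at -1.68 (SE 0.52). The call was lost without the mutants of day 2 (mean -0.04, adjusted p = 0.944), without the siblings of day 2 (0.16, adjusted p = 0.0978) and over all wells (0.11, adjusted p = 0.0672).

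With sort day as a block 3 more lists were called. Antigen presentation genes were higher (adjusted p = 0.0429, against 0.144 without the block; 0.817 with an estimated correlation): the invariant chain genes cd74a and cd74b had log2 folds of 2.23 (SE 0.53) and 1.83 (SE 0.41) and adjusted p of 0.000635 and 0.00703 with the block, and the MHC class II gene mhc2dab stood at 2.13 (SE 0.61). Of the 10 members 4 were higher and 3 lower on both days, with cd40 at -0.84 (SE 0.53), and 3 passed adjusted over the list alone. Genes of migration and the cytoskeleton were higher (adjusted p = 0.0191, against 0.0594), 14 of 35 on both days and 6 lower on both, with the myosin gene myo1f at 1.29 (SE 0.42); without the mutants of day 2 the mean was -0.06 (adjusted p = 0.975). Muscle markers were lower (adjusted p = 0.0445, against 0.408), 7 of 8 on both days; they made up 0.159% and 0.136% of the UMIs of sibling and mutant macrophage-like wells on day 1 and 0.0339% and 0.0176% on day 2. The estimated correlation gave adjusted p of 0.817 and 0.880 for these lists, and without the mutants of day 2 the muscle list was called in the opposite direction (mean 0.53, adjusted p = 0.000833). Without the siblings of day 1 its mean was 1.06 (adjusted p = 0.508).

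The remaining 15 lists were not called by camera in either fit, with adjusted p from 0.191 to 0.871 without the block. Stress and dissociation genes moved in both directions (fry mixed test, adjusted p = 0.0179), a call lost with sort day as a block, over all wells and when any pool was left out: the heat shock genes hsp70l and hspb1 stood at 2.59 (SE 0.53) and 1.86 (SE 0.45) and hspa8 (ENSDARG00000068992) at -0.75 (SE 0.20), of which hsp70l and hspa8 passed with the block (0.000677 and 0.0221). Of 31 genes of lysosomes and phagocytosis, the protease gene ctsk was higher (3.08, SE 0.60; 0.00760 with the block), ctsl.1 stood at -1.83 (SE 0.93) and the scavenger receptor gene stab1 at -2.06 (SE 0.57). Macrophage markers moved apart, with cd74a and cd74b higher and 2 genes of mfap4 lower, the second (ENSDARG00000090783) at -1.14 (SE 0.33; 0.0443 with the block). In the NADPH oxidase and granule list 5 of 8 members were lower on both days, with cybb at -0.79 (SE 0.35). In the list of Shp1 signalling 5 of 14 members were higher and 5 lower on both days; jak2 and stat3, a kinase and a transcription factor of cytokine signalling, stood at 1.58 (SE 0.68) and 1.29 (SE 0.63), adjusted p of 0.732 and 0.772. Among interferon genes irf7 stood at 1.34 (SE 0.41, adjusted p = 0.389). In the alternative and repair list 6 of 11 members were higher on both days and 2 lower. Medians of the lists of complement, cell cycle, glycolysis, apoptosis, the mitochondrial genome, microglia, thrombocyte and epidermis genes were 0.25, 0.01, 0.09, -0.02, -0.08, 0.01, 0.39 and -0.08. The median and the test differed in sign for Shp1 signalling, interferon and microglia genes, and the mean and the test for apoptosis genes.

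**Figure D3:**
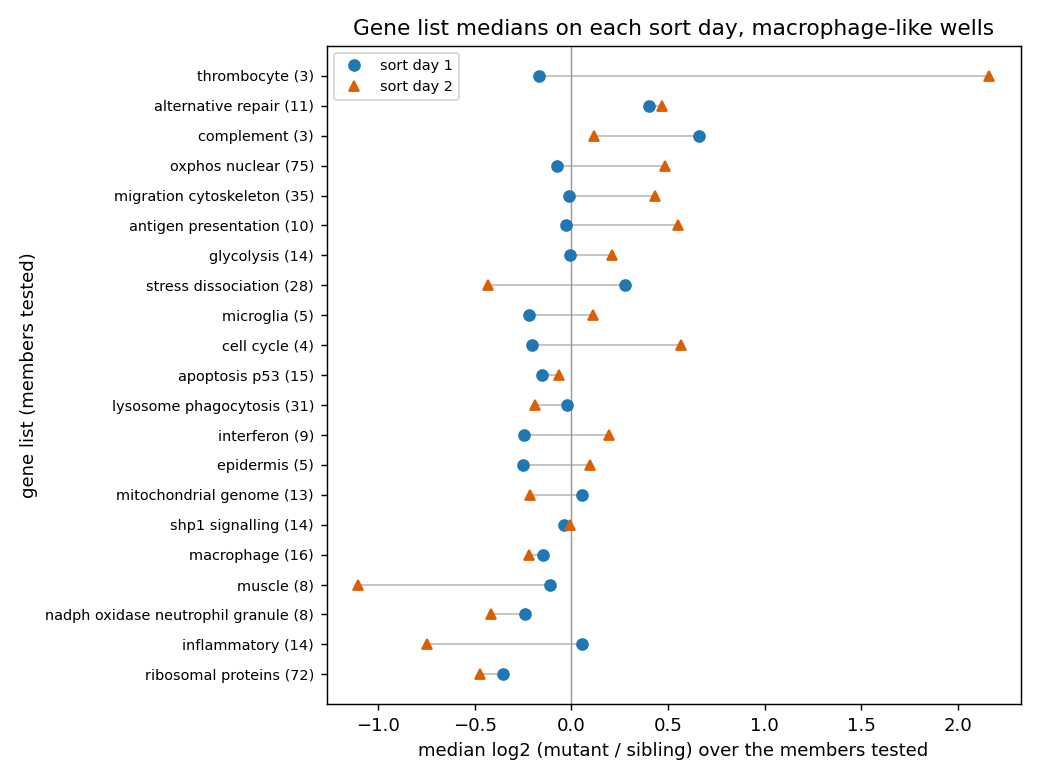
Median log2 ratio of mutant to sibling pools over the members tested of each of the 21 gene lists in macrophage-like wells (number of members in brackets); circles are sort day 1 and triangles sort day 2. Ribosomal protein genes lie below 0 on both days, at -0.35 and -0.47.

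Over all wells kept, which needs no cell classes, no gene passed of 8177 tested. At an unadjusted p under 0.05 there were 271 genes, DESeq2 called 27, and edgeR with sort day as a block called si:dkey-119g10.4 and an unnamed gene (ENSDARG00000026039), both higher in mutants. The log2 ratios of the 2 days had a Pearson r of -0.0972 (Spearman rho -0.0832) across genes. RNA of other tissues differed between the pools, on day 1 within the plate that both genotypes shared: muscle markers made up 0.161% of the UMIs in siblings and 1.34% in mutants of day 1, against 0.0367% and 0.0194% on day 2, and markers of brain and retina 0.160% in siblings and 0.00481% in mutants of day 2. Neutrophil markers made up 0.0244% in siblings and 0.0380% in mutants of day 1, and 0.0519% and 0.120% on day 2, and in macrophage-like wells 0.0112% and 0.0496%, and 0.0531% and 0.0690%. Too few of their genes were tested there for the list to be tested with all pools. In macrophage-like wells it was tested only in fits without 1 pool, where the filter admits genes counted in a single pool. Its mean log2 change was 2.06 and 3.83 without the siblings of day 1 or of day 2, and 2.57 without the mutants of day 1. The list was not tested without the mutants of day 2, the pool with its highest share. These fits therefore cannot decide its direction. Leaving out wells rich in RNA of muscle, brain and retina, epidermis or mesenchyme, a choice made after seeing the data, gave 4 higher genes. Neutrophil markers did not count towards that limit. Over all wells kept, fits without 1 pool tested 9417 to 9799 genes, so their calls are not comparable.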

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

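The tests of free RNA and of variants near ptpn6 were chosen only after the results were seen; the others were written before. Several gene lists and cell classes moved one way on sort day 1 and the other on sort day 2, a difference that was not tested. Median log2 ratios, mutant over sibling, were 0.06 and -0.75 for inflammatory genes (day 2 minus day 1 -0.81), -0.07 and 0.49 for nuclear genes of oxidative phosphorylation (0.56), -0.03 and 0.55 for antigen presentation (0.58), and -0.01 and 0.43 for migration and cytoskeleton genes (0.45). The share of macrophage-like wells, mutant minus sibling, moved by -2.66 percentage points between the days (0.315 and -2.34), that of microglia-like wells by -8.945 (0.752 and -8.19), and that of mesenchyme-like wells by 9.66 (-0.880 and 8.78). On day 2 each genotype has its own plate, so a plate difference and a genotype difference cannot be told apart there. In wells outside the comparisons, those under 500 UMIs, si:dkey-6n3.3 stood at 4632 CPM on the mutant plate of day 2, and muscle markers held 0.543% of the UMIs on the plate of day 1.

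Genes such as si:dkey-6n3.3, anxa5b, ccl34b.8 and ctsk were higher in mutant macrophage-like wells on both days. Well numbers read in the wrong order on the shared plate are argued against. On day 2 alone 50 genes were picked each way. They differed by 1.75 log2 between the sibling and mutant wells of the shared plate. The share of random splits with as large a difference was 0.0001, the smallest these splits can give. The other order tried, column by column, gave 0.27. Under the row by row order, splits by columns 1-12 against 13-24, odd against even rows and odd against even columns gave -0.22, 0.39 and -0.27. Equal free RNA in every well is argued against on day 2, with a median ratio of 79.4 between macrophage-like wells and wells under 500 UMIs (252.5 and 2.69 UMIs of these genes per well), and stays open on day 1 (5.36, lower quartile 2.53, few low wells); RNA in proportion to a well's total was not tested, and these genes held 1.51% of the UMIs in low wells and 2.17% in macrophage-like wells of day 2. Variants linked to the mutated gene could reach ctsk, 1 of 52 called genes with a matched position to lie within 200 genes of ptpn6, and are argued against as the cause for most; si:dkey-6n3.3 and si:dkey-119g10.4 had no matched position. Loss of Shp1 in the cells themselves, other effects of the mutant embryos and the plates of day 2 stay open.

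RNA of muscle, retina and connective tissue was high on single plates. Muscle markers held 0.818% of the UMIs kept on the plate of day 1 (0.161% in siblings and 1.34% in mutants of that plate), retina markers 0.160% and mesenchyme markers 0.0400% on the sibling plate of day 2. Equal free RNA in every well is argued against as the whole cause: macrophage-like wells held 7.28, 6.99 and 11.5 times as many of these UMIs per well as wells under 500 UMIs with spike-ins (bootstrap lower bounds 5.55, 5.12 and 6.91), but the low wells held the higher share (muscle 0.543% against 0.145%, retina 0.125% against 0.0212%, mesenchyme 0.0396% against 0.0101%), so free RNA could be part of the cause. Whole cells of these tissues in a few wells fit 3 of 3 pairs of plate and tissue, since the 5% of wells richest in them held 84.4%, 88.8% and 78.4% of these UMIs; on the plates that were not high they held 26.1% and 13.2% for muscle but 70% and 54.9% for retina and 82.7% and 65.3% for mesenchyme, so for these 2 tissues the test does not set the high plate apart. Neither free RNA taken along with cells nor a biological explanation was tested, such as the genotype for muscle on the shared plate, and on day 2 genotype and plate coincide.

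Ribosomal protein genes were lower in mutant macrophage-like wells on both days. Depth per well is argued against on day 2, where it predicted 0.562% of the fall (upper bound 9.50%); on day 1 it predicted 20.05% (bootstrap interval 2.85 to 60.5), which leaves it open. A few genes taking most of the counts stays open, since other genes of like abundance changed by -0.06 and -0.16 log2 before scaling, against -0.27 and -0.21 for ribosomal genes. A different mix of clusters stays open too: within the cluster led by mfap4 the differences were -0.20 and -0.14 and within the cluster led by ctsk -0.33 and -0.13, close to the bound of -0.1 given their spread. Lower ribosomal transcript levels in cells without Shp1 could give the same values.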

How the results depend on the processing

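Leaving out wells rich in RNA of other tissues and clustering without leading genes were chosen only after the data were seen. For the 24 named genes, values were compared with the fit on genotype alone, in which only 3 of them passed. Of these values 355 kept their direction and side of the threshold, 95 newly passed, 3 no longer passed and none reversed. For the genes that did not pass in that fit, a value that stayed the same had still not passed. Changes of wells or clustering within the fit with sort day were not counted. The 7 gene lists gave 40 the same, 10 stronger, 5 weaker and 8 reversed. The named genes had been chosen for moving the same way on both days, so their lack of reversals is no test of direction. Below, the cause was not tested where a result changed.

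In macrophage-like wells the count of 3 genes became 30 with DESeq2, 78 without the filter, 60 with sort day as a block and 0 at a minimum of 2000 UMIs, and ran from 5 to 131 leaving out each pool in turn. The 60 genes of the fit with sort day became 27 with DESeq2, 111 without the 2% of wells with most UMIs, 129 and 99 at resolutions 0.5 and 2, 104 without wells rich in other RNA and 121 clustered without leading genes. Over all wells the count of 0 became 27 with DESeq2, 226 without the filter, 2 with sort day and 4 without wells rich in other RNA, and ran from 0 to 287 leaving out each pool. With sort day, the 2 genes became 18 with DESeq2, 1 and 11 at minima of 500 and 2000 UMIs, 4 without the top 2%, 0 on thinned pools and 4 without wells rich in other RNA.

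The 3 lists called became 6 with sort day and 5 over all wells. With an estimated correlation 0 were called, which cannot decide the calls, since almost no list could pass with 2 pools per genotype. Mean log2 changes leaving out each pool ran from -0.80 to 0.13 for inflammatory genes (reversed without the siblings of day 2), from -3.02 to 1.06 for muscle (reversed without the siblings of day 1, and at 0.53 without the mutants of day 2), and, reversed without the mutants of day 2, from -0.036 to 0.36 for oxidative phosphorylation, from -0.061 to 0.35 for migration and from -1.01 to 1.44 for the cell cycle. Over all wells the muscle mean was 2.43 and the cell cycle mean -0.30, both reversed. The fry mixed call of stress genes became 0 with sort day, over all wells, with microglia-like wells and without any pool. The log2 fold of ptpn6 ran from -6.07 to 0.23. In the fits without 1 pool the lone pool is assumed to vary like the other groups, and the filter admits genes counted in a single pool. They tested 5478 to 5737 genes in macrophage-like wells instead of 4740, and 9417 to 9799 over all wells instead of 8177. Their counts and list means thus rest in part on other genes than the main fit.

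At 500 UMIs macrophage-like wells made up 47.9% of mutants and 50.3% of siblings of day 1 and 57.1% of siblings of day 2, and unnamed wells 35.6%, 34.2% and 22.4%; the median of genes in siblings of day 1 fell to 1610. The macrophage-like shares at 500 UMIs include a cluster of 82 wells led by pdk2, noct and cxcr4, as the largest unnamed cluster was. It took the name with 0 macrophage markers among its 10 leading genes. At 2000 UMIs mutants of day 1 had 50.8% macrophage-like and 31.7% unnamed wells. There a cluster of 19 wells led by ranbp10, whose counterpart was unnamed in the main setting, was called macrophage-like. Without the top 2%, mutants of day 1 had 36.1% unnamed wells. In that setting a cluster of 28 wells led by grna.2 and icn, whose counterpart was unnamed in the main setting, was called epidermis-like. Mesenchyme-like wells of siblings of day 2 were 0.513% without the top 2%, against 1.51% at resolution 0.5. The other 85 shares stayed the same. Depth limits genes such as ptpn6, at 0 to 11 UMIs per pool.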

Other observations

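The overlap between cell classes was looked at only after the results were seen. Many differences seen in macrophage-like wells were also present in unnamed wells. Of 4103 genes tested in both, 47 were called in macrophage-like and 41 in unnamed wells with sort day as a block, and 15 were called in both, all in the same direction (0.470 would be shared by independent lists, and these lists come from the same plates, so a plate difference would give the same). The 15 included anxa2, anxa5b, cd74a, cd74b, ctsk, marcksl1b, gpr84, acod1 and si:dkey-6n3.3. In microglia-like wells no gene passed of 1953 tested with edgeR (81 at an unadjusted p under 0.05, and 0 with sort day as a block). Of the 34 macrophage-like calls tested there 32 had the same direction, against 64.6% of all 1947 genes tested in both classes, and a plate difference would give this too. In unnamed wells no gene passed without the block of 5165 tested (169 unadjusted), and 17 were higher and 29 lower with it.

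Single tissue genes stood out in single pools: opn1sw, a cone opsin, had 10407 UMIs in siblings of day 2 against 12, 4 and 0 in siblings of day 1, mutants of day 1 and mutants of day 2. The parvalbumin gene pvalb2 had 9329 UMIs in mutants of day 1 against 729 in siblings of day 1 and 208 and 57 on day 2. The lysozyme gene lyz had 799 UMIs in mutants of day 2 against 9 in siblings of day 2 and 0 in each pool of day 1. On the mutant plate of day 2 si:dkey-6n3.3 was detected in all wells of every cluster, from 610 CPM in the cluster led by grna.2 and icn to 8475 in the cluster led by pdk2 and cxcr4. On the shared plate of day 1 no cluster had it in all mutant wells, and its direction varied. Mutants stood lower in the clusters led by ranbp10 (144 CPM in siblings, 67.8 in mutants) and grna.2 (86.2 and 58.2). These values rest on 2 and 4 UMIs, and on 6 and 8. Mutants stood higher in every other cluster, with 80.5 and 1089 CPM in the cluster led by pdk2 but 56.9 and 112 in the cluster led by sftpba.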
